A study of Mus musculus with 4 samples.

How the data were processed

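RNA was measured by bulk sequencing in dorsal root ganglia, the clusters of sensory neurons beside the spinal cord, from mice aged 10 weeks and labelled as a mixed strain. Per the labels, ganglia were dissected in oxygenated artificial cerebrospinal fluid, RNA was extracted with TRI reagent and a column kit, and libraries followed standard Illumina protocols. There were 2 wild type samples and 2 Prdm12 mutant samples. Per the labels, the mutants carried a null and a floxed allele of Prdm12 with 1 copy of Avil-CreERT2, a tamoxifen-inducible Cre recombinase driven by the sensory neuron gene Avil. Each sample took its group and replicate number from its own title.

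The authors deposited a matrix of FPKM values (read fragments scaled to transcript length and to the mapped fragments of the library) for 14405 genes in the 4 samples. Tested on the values, each gene in it had at least 1 FPKM in at least 1 sample. The authors also deposited a list of 150 genes with the group FPKM, a log2 fold change, a p-value and a q-value per gene, in the column format of Cuffdiff per the file headers. The file's name gives limits of 1 FPKM, an absolute log2 fold change of 1 and a false discovery rate of 0.05. The group FPKM in that list equalled the mean of the group's 2 matrix columns to within 0.000735%. Per the submitters' processing notes, CASAVA, TopHat2 2.1.2 and Cufflinks 2.2.1 were used with the mouse build mm10. The role and settings of each tool, the strandedness of the libraries and the method of library scaling are not given in the sources used here. One log2 fold change in the list, that of H2-Ea-ps, is a spreadsheet error in place of a number, and some gene names in the matrix had become calendar dates. One such name occurred more than once and was kept as separate rows.

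FPKM values hold no read counts, and too few genes had low values in several samples to recover the worth of 1 read, so the sequencing depth is unknown and no counting interval is given. FPKM totals were 620018 and 674082 in wild type 1 and 2, and 629900 and 686830 in mutant 1 and 2. The multi-copy globin and histocompatibility genes can share reads with near-identical copies, so their single values are uncertain.

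The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance prior that follows mean expression. It covered the 14040 genes with a mean of at least 1 FPKM in either group, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. Fold changes are therefore on the log2(FPKM + 1) scale, mutant minus wild type, which understates the change of genes with few FPKM. Fold values in FPKM are ratios of group means. The fit had 2 residual degrees of freedom and borrowed 3.44 more from the other genes. An exact two-sided permutation test of 2 samples against 2 cannot give a p below 0.333. The labels do not say that the samples came from separate animals. The Y-linked gene Eif2s3y was at 21.3 FPKM in wild type 1 and at 0.0252 FPKM in wild type 2, so these 2 were not repeats of 1 source. The p-values measure the spread between these samples, which may be technical in part.

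Before the data were examined, 41 gene lists were written down for sensory neuron types, channels, other cell types and technical signs, and 39 of them had the 5 tested members needed. Each was tested with limma's camera with a preset correlation between genes of 0.01, and the p-values were adjusted over the lists. Beside it, camera was run with an estimated correlation and fry was run as a test of each list alone. Single members were also adjusted over the list alone. Genes are named by a rule set at the same time. It takes Prdm12 and Avil, and the 10 genes in each direction that pass the test without overlap between the groups. Where fewer pass, it fills up with the largest moderated t among genes of at least 5 FPKM in either group without overlap, given as values and not as calls. From each list it takes up to 3 members that pass over the list alone, or otherwise the 2 with the highest mean, and from the authors' list the 5 largest rises and falls among genes of at least 5 FPKM. Genes named outside the rule are said to be so. Some genes that the rule takes are not reported here. Coordinates come from GENCODE M21 on GRCm38, the same assembly as mm10.

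The script was tested on simulated data made from these samples' means and spread, 20 times for each setting, over 14040 genes. With 200 genes changed 4-fold, 89.4% were recovered past the adjusted threshold, and with 8-fold changes 97.8%. With 2-fold changes 0% were recovered past the adjusted threshold and 93.7% at an unadjusted p under 0.05. With 20 genes changed, 25% were recovered at 4-fold and 88% at 8-fold. Camera found a list shifted by 1 log2 unit in 20 of 20 simulations and an unshifted list in 0 of 20. The simulated genes varied independently of each other. The camera result therefore does not cover lists whose genes move together, such as Schwann cell and myelin markers, with an estimated correlation of 0.79.

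Alternatives changed 1 choice at a time: the pseudocount, the FPKM minimum, rescaling by median ratios, quantile normalization, the variance prior, a replicate block, the threshold and each sample left out. Figures were drawn with matplotlib 3.10.9. The mitochondrially encoded genes had 0 of 13 members in the matrix and were not analysed here.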

Results

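The data were FPKM values from bulk RNA sequencing of mouse dorsal root ganglia at 10 weeks of age, with 2 wild type and 2 Prdm12 mutant samples. The series' title concerns loss of Prdm12, a transcription factor of the pain-sensing neuron lineage, in development against loss in mature nociceptors. The comparison here asks how the transcriptome of the ganglia differed between mutant and wild type mice. The most abundant transcript was Ptgds in both wild type samples (13098 and 13055 FPKM) and Tmsb4x in mutant 1 (5963 FPKM). Over genes, Pearson's r between samples on log2(FPKM + 1) was 0.982 within wild type and 0.971 within mutant. It was highest between wild type 1 and mutant 1 (0.988) and lowest between wild type 1 and mutant 2 (0.964), so the samples did not group by genotype in this measure.

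Prdm12 was lower in both mutant samples than in both wild types. It stood at 7.58 and 10.7 FPKM in wild type and at 1.05 and 1.50 FPKM in the mutants, or 9.13 ± 2.19 against 1.27 ± 0.313 FPKM (SD, n = 2 each), 7.16-fold lower by the means. The log2 difference was -2.14 with a standard error of 0.213 and a 95% interval of -2.68 to -1.61. It did not pass over all genes (limma adjusted p = 0.180) and passed when adjusted over the list alone, that of nociceptor lineage transcription factors (limma adjusted p = 0.00133). The authors' deposited table gives a log2 change of -2.84 with q = 0.00742. Prdm12 (ENSMUSG00000079466.2) lies on chromosome 2 at 31640037 to 31655795 in mm10. Which exon is floxed is not given in the sources used here, and the FPKM of a whole gene may not show the loss of 1 exon. Avil, whose promoter drives the Cre, was at 101 ± 32.2 FPKM in wild type and 133 ± 44.0 FPKM in the mutants (SD, n = 2 each), with overlapping samples (log2 difference 0.39, limma adjusted p = 0.994). With each sample left out, its log2 difference ran from 0.05 without mutant 2 to 0.73 without mutant 1.

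Among the genes that differed most against their spread, those lower in the mutants included abundant secreted and transport genes. Ptgds, the lipocalin-type prostaglandin D synthase, was at 13077 ± 30.8 FPKM in wild type and 3113 ± 124 FPKM in the mutants (SD, n = 2 each), a log2 difference of -2.07. Fgfbp1, a carrier of fibroblast growth factors, was at 55.5 ± 1.23 and 11.4 ± 1.92 FPKM (log2 difference -2.20), and the P-type ATPase gene Atp13a5 at 26.2 ± 3.85 and 4.69 ± 1.00 FPKM (-2.26). Nnat had a log2 difference of -1.80, the glutamine transporter gene Slc38a3 of -1.52, Dapl1 of -1.76, the organic anion transporter gene Slc22a6 of -1.92, Mgst2 of -1.56 and the muscle light chain gene Myl2 of -1.58. On the higher side, Bglap, which encodes osteocalcin, was at 1.59 ± 0.0828 FPKM in wild type and 5.29 ± 0.0149 FPKM in the mutants (log2 difference 1.28). The globin genes Hba-a1 (1.06), Hbb-b1 (0.90) and Hbb-b2 (0.93), the erythroid haem synthesis gene Alas2 (0.83) and the carbonic anhydrase gene Car1 (0.74) had higher values in both mutants. So did the class II histocompatibility gene H2-Eb1 (1.41), Fhit (0.78), the ciliary neurotrophic factor gene Cntf (0.74) and the unplaced transcript 5730408K05Rik (0.84). These genes are given as values and not as calls, since with limma 0 of 14040 genes passed an adjusted p of 0.05 and the smallest adjusted p was 0.175. At an unadjusted p under 0.05, 190 genes were higher and 422 lower, 612 in all where chance alone gives 702. Without mutant 1 there were 1807, 880 higher and 927 lower. After rescaling by median ratios the split was 251 higher and 366 lower, and after quantile normalization 268 and 357. Groups did not overlap for 1753 genes higher and 2751 genes lower, 32.1% of those tested, where chance gives 33.3%. Without wild type 1, 5 genes passed (Eif2s3y, Xist, Csrp3, Ddx3y and Snurf, named after their values were seen), for which wild type 2 alone stood for the wild type.

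**Figure D1:**
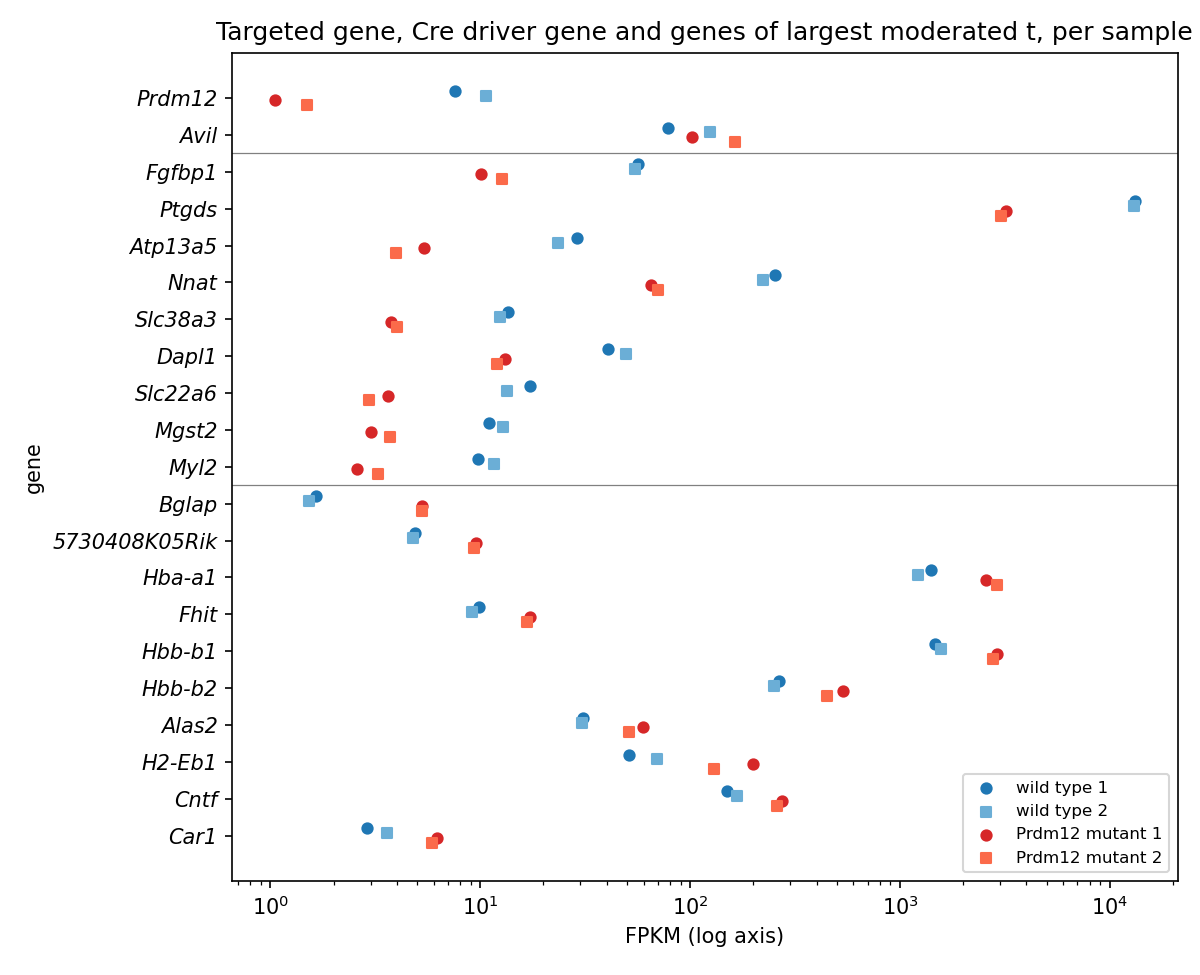
FPKM of Prdm12, Avil and the genes with the largest moderated t in each direction, on a log axis, 1 point per sample (circles replicate 1, squares replicate 2, blue wild type, red mutant). Prdm12 was at 7.58 and 10.7 FPKM in wild type and at 1.05 and 1.50 FPKM in the mutants, and Avil overlapped between the groups.

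In the main test, the lists of genes of pain-sensing neurons did not pass. Of 17 peptidergic nociceptor genes, 7 were higher and 2 lower in both mutants than in both wild types, with a median log2 difference of 0.11 (camera adjusted p = 0.272). Calca, which encodes the neuropeptide CGRP, was at 1704 ± 222 FPKM in wild type and 1715 ± 69.8 FPKM in the mutants (SD, n = 2 each), and the substance P gene Tac1 at 372 ± 4.50 and 414 ± 48.1 FPKM. Of 22 nonpeptidergic nociceptor genes, 1 was higher and 6 lower without overlap (median -0.09, adjusted p = 0.0762), with Cd55 at a log2 difference of -0.57 and Scg3 at -0.06. Of 13 nociceptor lineage transcription factors, Prdm12 passed over the list alone and the list did not (median 0.24, adjusted p = 0.172). Of 15 pruriceptor genes, which mark itch-sensing neurons, 7 were lower and 1 higher without overlap (median -0.29, adjusted p = 0.0745). Nppb was at 60.8 ± 10.6 and 42.0 ± 2.83 FPKM, and Nts at 28.7 ± 27.2 and 53.8 ± 13.6 FPKM. The C-LTMR genes, of low-threshold touch fibres, had a median of 0.17 (adjusted p = 0.333), with Th at 0.44 and Rarres1 at 0.08. The 14 pan-neuronal genes had a median of 0.25 (adjusted p = 0.0549), with Uchl1 at 0.17 and Tubb3 at 0.34. Several of these lists passed with 1 sample left out or under another setting. With a replicate block, the lineage transcription factors (camera adjusted p = 0.0418) and the pan-neuronal genes (camera adjusted p = 0.00141) passed. The nonpeptidergic list passed without wild type 1 (median -0.37, adjusted p = 1.09e-05) and without mutant 2 (-0.28, adjusted p = 0.000147), but its median was 0.02 without wild type 2 and 0.06 without mutant 1. It also passed after rescaling by median ratios (adjusted p = 0.0440) and after quantile normalization (adjusted p = 0.0478). Pruriceptor genes passed without mutant 2 (median -0.20, adjusted p = 0.0270), after rescaling by median ratios (adjusted p = 0.0440) and with a minimum of 5 FPKM (adjusted p = 0.0180). Without wild type 2 and without mutant 1, the lineage transcription factors passed (medians 0.49 and 0.49, adjusted p = 0.0209 and 0.0348), as did the pan-neuronal genes (0.44 and 0.53, adjusted p = 0.000221 and 0.000504). The pan-neuronal genes also passed after rescaling by median ratios (adjusted p = 0.0440) and with a minimum of 5 FPKM (adjusted p = 0.0459), while their median was -0.02 without wild type 1 and -0.13 without mutant 2. C-LTMR genes passed without wild type 2 (median 0.48, adjusted p = 0.00746). The median of the peptidergic list was -0.19 without mutant 2.

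Some sensory lists passed with the preset correlation. The Mrgpr receptor family, which includes itch and nociceptor receptors, fell by a median of 0.45 on the log2 scale (camera adjusted p = 0.0226, and 0.772 with an estimated correlation). Of its 13 members, 4 were lower without overlap and 0 higher. Mrgpra3 was at 17.3 ± 3.28 FPKM in wild type and 11.8 ± 3.24 FPKM in the mutants (SD, n = 2 each), and Mrgpra6 at 24.7 ± 9.21 and 21.0 ± 0.414 FPKM. The 5 cold-sensing neuron genes fell by a median of 0.45 (adjusted p = 0.0226, and 0.772 with an estimated correlation). Penk, the proenkephalin gene, was at 16.7 ± 1.69 and 9.38 ± 5.14 FPKM and was lower in both mutants, while Rgs2 was at 9.49 ± 0.0467 and 10.5 ± 0.142 FPKM. Genes of myelinated mechanoreceptors and proprioceptors rose by a median of 0.18 over 26 genes (adjusted p = 0.0131), voltage-gated sodium channels by 0.24 over 10 genes (adjusted p = 0.0136) and potassium channels by 0.20 over 27 genes (adjusted p = 0.00800). With an estimated correlation these 3 lists did not pass (camera adjusted p = 0.772 for each). With all 4 samples their medians were no larger than the 0.25 of the pan-neuronal genes, so the data do not set them apart from neuronal genes at large. In these 3 lists 5, 2 and 4 members were higher without overlap and 3, 0 and 1 lower, and 0 members passed over the list alone. Pvalb, also a member of the fixed skeletal muscle list, had a log2 difference of 0.30. It was at 226 and 401 FPKM in wild type 1 and 2, and at 220 and 624 FPKM in mutant 1 and 2. Ldhb had a log2 difference of 0.13, Scn7a of 0.21, Kcnip4 of 0.04 and Kcnip2 of 0.09. The 3 rises were lost without wild type 1 (adjusted p = 0.432 for the mechanoreceptor and sodium channel lists and 0.901 for potassium channels) and without mutant 2 (0.894, 0.839 and 0.440). The Mrgpr call was lost without wild type 2 (median -0.20, adjusted p = 0.0922), and its median was -0.27 without mutant 1 and -0.16 without mutant 2. The median of the cold-sensing genes was -0.25 without mutant 1. Without wild type 2 and without mutant 1 the rises were larger, at 0.40 and 0.38 for mechanoreceptors, 0.47 and 0.57 for sodium channels and 0.48 and 0.36 for potassium channels.

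Other channel and peptide lists did not pass in the main test. With a replicate block the other transduction channels passed (camera adjusted p = 0.0183). TRP channels had a median of 0.02 and a mean of -0.14, and the test pointed down (adjusted p = 0.254). Trpm3, a heat-activated channel, passed over the list alone, at 8.27 ± 0.734 FPKM in wild type and 3.86 ± 0.793 FPKM in the mutants (SD, n = 2 each, log2 difference -0.94, limma adjusted p = 0.496 over all genes). Adjusted p was 0.0750 for other transduction channels (median 0.18, P2rx3 0.19, Tmem120a 0.18), 0.183 for voltage-gated calcium channels (median 0.08, Cacnb3 0.45, Cacng7 0.10) and 0.362 for the opioid and cannabinoid system (median 0.31, Mgll 0.46). It was 0.591 for neuropeptides (median 0.06) and 0.149 for nerve injury response genes (median 0.13, Crip1 0.22, Hspb1 0.11). The other transduction channels passed without wild type 2 (median 0.33, adjusted p = 0.0227), without mutant 1 (0.41, adjusted p = 0.0281) and with a minimum of 5 FPKM (adjusted p = 0.0261), and their median was 0.03 without wild type 1 and 0.02 without mutant 2. The nerve injury genes passed without wild type 1 (median 0.16, adjusted p = 0.000782).

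Schwann cell and myelin markers rose, by a median of 0.55 on the log2 scale over 19 genes (camera adjusted p = 3.59e-09, and 0.772 with an estimated correlation), and 11 of them were higher in both mutants than in both wild types. The rise stood mostly in 1 library. Pmp22, which encodes a peripheral myelin protein, was at 3153 and 2752 FPKM in wild type and at 3404 and 6144 FPKM in the mutants. Without mutant 2 the median was 0.13 (adjusted p = 0.00288), and without mutant 1 it was 0.94. Cholesterol synthesis genes rose with them, by a median of 0.29 over 19 genes (adjusted p = 0.000386, and 0.772 with an estimated correlation), with Hmgcs1 at 0.24 and Msmo1 at 0.31. Without mutant 2 that median was -0.05 (adjusted p = 0.928), without wild type 2 it was 0.16 (adjusted p = 0.208), and without mutant 1 it was 0.57. Satellite glia markers had a median of 0.18 (adjusted p = 0.0910), with Apoe at -0.06 and Sparc at 0.08, and passed without wild type 1 (median 0.24, adjusted p = 0.0201). Non-myelinating Schwann cell markers had a median of 0.23 (adjusted p = 0.436), and fry pointed down where camera pointed up. In that list the retinaldehyde dehydrogenase gene Aldh1a1 passed over the list alone, at 113 and 117 FPKM in wild type and at 51.7 and 50.8 FPKM in the mutants (log2 difference -1.15).

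Fibroblast and meninges markers fell by a median of 0.27 over 19 genes (camera adjusted p = 0.000102), with 7 lower and 1 higher without overlap. With an estimated correlation the list did not pass (adjusted p = 0.772). Igf2 and the GABA and taurine transporter gene Slc6a13 passed over the list alone. Igf2 was at 302 ± 76.9 FPKM in wild type and 106 ± 22.2 FPKM in the mutants, and Slc6a13 at 72.7 ± 7.35 and 29.4 ± 3.79 FPKM (SD, n = 2 each). The list call was lost without wild type 1 (adjusted p = 0.0548) and without mutant 2 (median -0.05, adjusted p = 0.191), and the median was -0.56 without mutant 1. Endothelial markers had a median of -0.13 (adjusted p = 0.119, and 0.0196 without mutant 1 at a median of -0.28; Ly6c1 0.14, Egfl7 0.07) and mural cell markers of 0.07 (adjusted p = 0.655; Tagln 0.05, Acta2 -0.07). Skeletal muscle and adipocyte markers differed between libraries of 1 group more than between the groups. The muscle list's median deviation from the mean of the 4 samples was -1.20 and 1.40 in wild type 1 and 2, and -2.18 and 2.32 in mutant 1 and 2. For adipocyte markers it was -0.67, 0.11, -1.30 and 1.75 in the same order, and Fabp4 was at 249, 484, 153 and 1328 FPKM and Cfd at 184, 202, 96.2 and 757 FPKM. Neither list passed in the main test (camera adjusted p = 0.171 and 0.272). With a replicate block the adipocyte list passed (camera adjusted p = 0.0435). Muscle markers passed in opposite directions without mutant 1 (median 2.19, adjusted p = 0.0196) and without mutant 2 (-2.39, adjusted p = 1.13e-12), and without wild type 1 (-1.46, adjusted p = 9.19e-07). Adipocyte markers did so without mutant 1 (1.97, adjusted p = 1.11e-09) and without mutant 2 (-1.08, adjusted p = 8.04e-11), while the muscle gene Myl2 passed over the list alone at 10.7 ± 1.35 and 2.92 ± 0.469 FPKM. Bone and cartilage markers had a median of 0.40 (adjusted p = 0.149, and 0.0326 without wild type 1), and 3 passed over the list alone, Bglap and Bglap2 (0.81) higher and Comp (-0.72) lower. Of the spinal cord markers 2 were tested, too few for a list test, Gfap with a log2 difference of -0.02 and Aqp4 of 0.11.

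Erythrocyte markers rose by a median of 0.83 (camera adjusted p = 3.59e-09, and 0.738 with an estimated correlation), and 6 of 7 passed over the list alone. Hba-a1 was at 1311 ± 142 FPKM in wild type and 2739 ± 245 FPKM in the mutants (SD, n = 2 each), Hbb-b1 at 1522 ± 73.1 and 2849 ± 89.3 FPKM, and Hbb-bs at 173 ± 68.2 and 301 ± 2.72 FPKM. T cell, B cell and neutrophil markers rose by a median of 0.44 (adjusted p = 4.09e-07, and 0.738 with an estimated correlation), with 9 of 16 higher without overlap and 0 lower. Their most abundant members overlapped between the groups, S100a8 at 964 ± 178 and 1346 ± 493 FPKM and S100a9 at 526 ± 299 and 696 ± 65.6 FPKM. The median of the lymphocyte and neutrophil list was 0.27 without wild type 1. The MHC class I and II genes rose by a median of 0.27 (adjusted p = 0.000102), with 8 of 16 higher and 1 lower without overlap. With an estimated correlation that list did not pass either (adjusted p = 0.772). H2-Eb1, at 60.3 ± 12.8 and 164 ± 48.7 FPKM, passed over the list alone. Without mutant 1 the list did not pass (median 0.12, adjusted p = 0.127), and the median was 0.14 without wild type 1, 0.47 without wild type 2 and 0.46 without mutant 2. Macrophage markers did not pass (median -0.01, adjusted p = 0.645), with their mean above 0. They passed in opposite directions without mutant 1 (median -0.20, adjusted p = 0.0314) and without mutant 2 (0.22, adjusted p = 3.56e-05). Cd74 had a log2 difference of 0.45 and Lyz2 of -0.09. Interferon response genes (median 0.11, adjusted p = 0.149; Ifi27 0.19, Bst2 0.24) and cytokine and chemokine genes (median -0.04 with a mean of 0.02, adjusted p = 0.787; Ccl11 0.12, Cxcl12 -0.26) did not pass with all 4 samples. Without mutant 2 the interferon response genes passed (adjusted p = 0.0195).

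**Figure D2:**
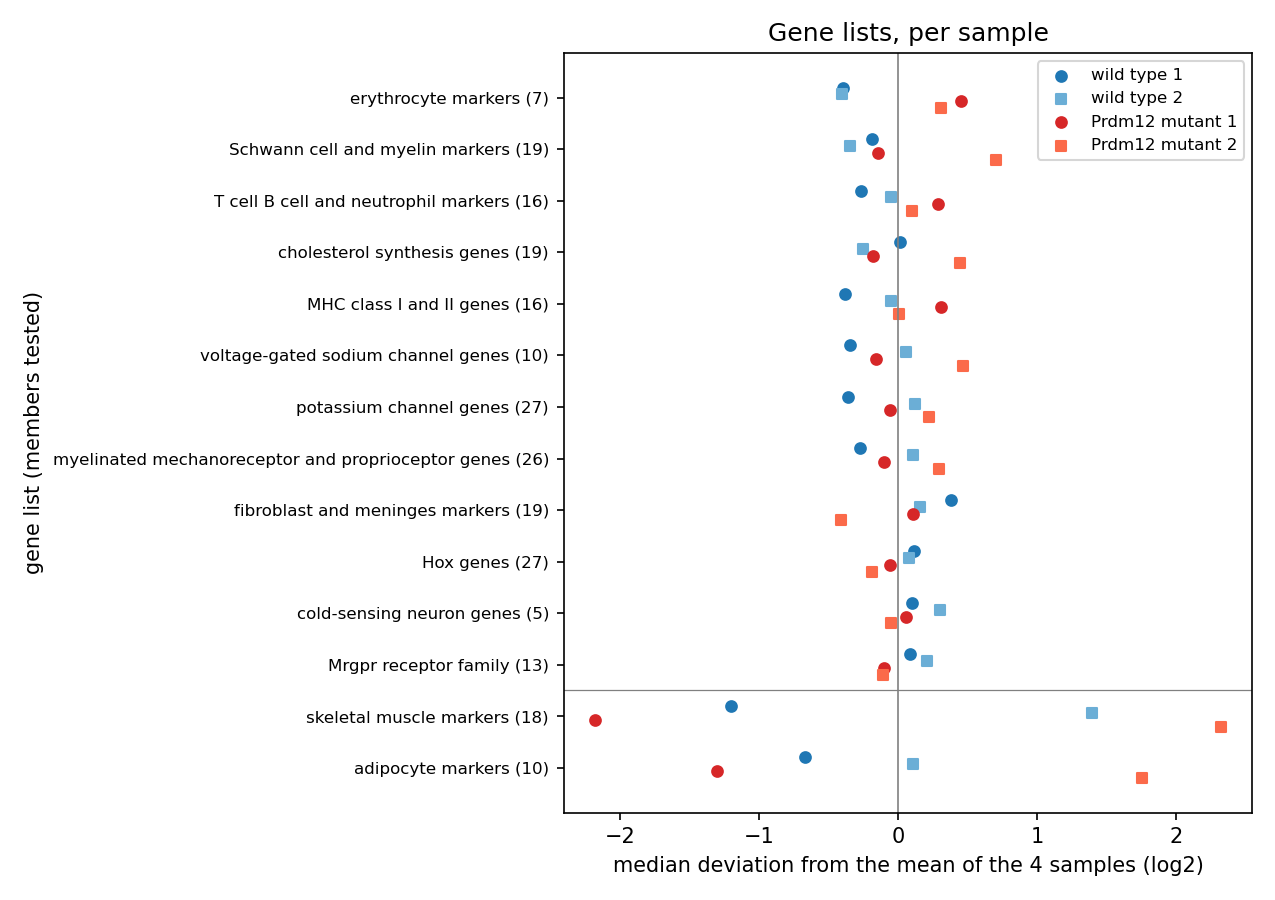
Median deviation of each gene list from the mean of the 4 samples, on the log2 scale, 1 point per sample (circles replicate 1, squares replicate 2, blue wild type, red mutant). The 12 lists above the line passed camera with the preset correlation and 0 passed with an estimated one. The muscle markers below the line ran from -2.18 in mutant 1 to 2.32 in mutant 2.

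Hox genes, which mark the position of cells along the body axis, fell by a median of 0.29 over 27 genes (camera adjusted p = 2.45e-05), with 15 lower and 2 higher without overlap. With an estimated correlation the list did not pass (adjusted p = 0.738), and 0 members passed over the list alone. Hoxc6 was at 20.8 ± 3.59 FPKM in wild type and 15.1 ± 0.431 FPKM in the mutants, and Hoxa10 at 27.5 ± 5.77 and 21.3 ± 4.20 FPKM (SD, n = 2 each). Heat shock genes (median 0.08, adjusted p = 0.25; Hspa8 0.10, Hsp90ab1 0.17), immediate early genes (median 0.07, adjusted p = 0.123; Jund -0.04, Klf2 -0.21), oxidative phosphorylation genes (median 0.05, adjusted p = 0.149; Ndufa4 0.24, Cox6c 0.27) and cytosolic ribosomal protein genes (adjusted p = 0.423; Rplp1 -0.08, Rpl38 0.35) did not pass with all 4 samples. Heat shock genes (median 0.23, adjusted p = 0.0281) and oxidative phosphorylation genes (0.15, adjusted p = 0.0407) passed without mutant 1, and immediate early genes without wild type 1 (0.13, adjusted p = 0.0124) and without mutant 2 (0.15, adjusted p = 0.000223). The ribosomal list had a median just below 0 and a mean of 0.04. The sex-linked genes separated 1 library from the rest (list adjusted p = 0.149, and 3.76e-10 without wild type 1). Eif2s3y was at 21.3 FPKM in wild type 1, 24.7 in mutant 1 and 23.2 in mutant 2, and at 0.0252 in wild type 2. Ddx3y was at 18.4, 16.8 and 11.3 FPKM in the same samples and listed at 0 in wild type 2. The labels give no sex. Both genes lie on the Y chromosome. By their values wild type 2 appeared to differ in sex from the other samples, which leaves the groups unbalanced for sex. Over all lists, 12 of 39 passed with the preset correlation, 8 higher and 4 lower, 0 with an estimated correlation (smallest adjusted p 0.738), and 0 with fry (smallest adjusted p 0.308, and 0.0638 for changes in either direction). Of 557 list members tested, 16 passed over the list alone.

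The authors' deposited table lists 150 genes, 129 lower and 21 higher in the mutants, with q from 0.00742 to 0.0460. These come from the same 4 samples and are not independent evidence. Of the 150 genes, 149 matched a gene of the matrix by name. The other entry lists Hba-a1 and Hba-a2 together, at 1311 FPKM in wild type and 2739 FPKM in the mutants. These are the means of Hba-a1 in the matrix, which was higher in both mutants, but the entry is left out of the counts below. All 149 had the same direction here, 116 had an unadjusted limma p under 0.05 and 0 passed after adjustment. Both mutants lay on one side of both wild types for 118 of the 129 lower genes and for 7 of the 20 higher ones. The 7 include the Y-linked gene Eif2s3y, at 21.3 and 0.0252 FPKM in wild type 1 and 2 against 24.7 and 23.2 FPKM in the mutants. Its rise thus follows wild type 2. The lower genes were below the wild type mean in both mutants for 129 of 129, whereas 8 of 20 higher genes were above it in both. The largest falls in the authors' deposited table with at least 5 FPKM were Myh2, Mybpc1, Csrp3, Prdm12 and Myh1. Of these, the 4 muscle genes were high in wild type 2, with Myh2 at 1.05 and 11.3 FPKM in wild type 1 and 2 against 0.436 and 0.861 FPKM in the mutants. Mybpc1 was at 0.916 and 9.98 against 0.401 and 0.829 FPKM, Csrp3 at 2.83 and 18.4 against 1.36 and 1.14 FPKM, and Myh1 at 2.71 and 28.4 against 1.06 and 3.62 FPKM. The largest rises were Eno1b, Pon1, Aqp12, Myh4 and Ces1d. Eno1b, an enolase gene with a near-identical copy, was at 18.0 FPKM in mutant 1 and at 1.07 FPKM or less in the others. The authors' deposited table places it on chromosome 4 and the annotation used here on chromosome 18, so which enolase gene was counted is uncertain. Myh4 was at 2.12 and 22.0 FPKM in wild type and at 0.490 and 70.9 FPKM in the mutants. Pon1 was at 11.3 FPKM in mutant 2 and between 1.55 and 1.61 FPKM in the others, and Ces1d at 39.7 FPKM in mutant 2 against 4.02 in mutant 1. Aqp12 was at 2.94 ± 1.46 FPKM in wild type and 9.87 ± 4.56 FPKM in the mutants (SD, n = 2 each).

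**Figure D3:**
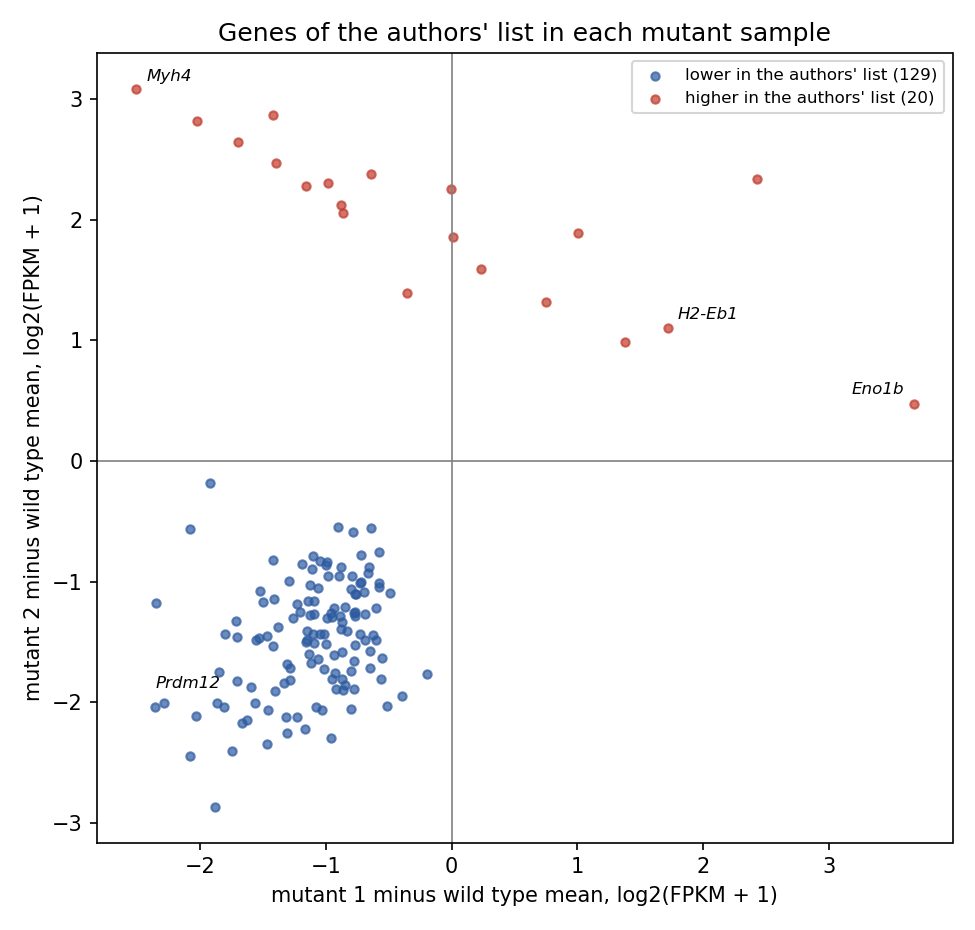
Difference of each mutant sample from the wild type mean, mutant 1 against mutant 2, on log2(FPKM + 1). Shown are the 149 genes of the authors' deposited table that matched the matrix by name. The 129 lower genes (blue) lay below 0 in both mutants, and 8 of the 20 higher genes (red) lay above 0 in both.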

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

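With limma, 0 genes passed an adjusted p of 0.05 under the other pseudocounts, FPKM limits, scalings and variance priors, and at a threshold of 0.1. With each sample left out in turn the count was 0 to 5, the 5 being without wild type 1. Where an arm keeps 1 sample, that sample is assumed to vary like the other group. The genes at an unadjusted p under 0.05 numbered 400 with a minimum of 5 FPKM, where fewer genes were tested, and 440 to 1807 with each sample left out, the highest without mutant 1. The lists that passed numbered 0 with an estimated correlation, 0 with fry, and 14 to 20 with each sample left out. For the Mrgpr (-0.005), cold-sensing (-0.2) and Hox (-0.012) lists the estimated correlation lay below the preset 0.01. A higher correlation between genes therefore does not account for the loss of these calls. In the other lists that passed in the main test it was higher than the preset, from 0.079 to 0.90. What else removed the calls, with an estimated correlation or with fry, was not tested. The log2 difference of Prdm12 ran from -2.37 to -1.92 with each sample left out. Among lists that passed in the main test or in the alternative, the direction of the test turned for macrophage markers (-0.20 without mutant 1, range -0.20 to 0.22), muscle markers (2.19 without mutant 1, range -2.39 to 2.19), adipocyte markers (-1.08 without mutant 2, range -1.08 to 1.97) and cholesterol synthesis genes (-0.0487 without mutant 2, range -0.0487 to 0.57). For these the cause was not tested. Over the alternatives the medians of 24 of 39 lists lay on both sides of 0. Schwann cell and myelin, T cell, B cell and neutrophil, erythrocyte and Hox lists kept their calls in all 13 alternatives that used the preset correlation, and cold-sensing genes in the 12 that could be run. With a replicate block 61 genes passed, 3 higher and 58 lower, 54 of them in the authors' list, the unadjusted count was 1474, and Prdm12 was at -2.14 with an adjusted p of 0.0250. Deviations of samples with the same number correlated at 0.481 over genes. With 2 samples per group, pairing unlike numbers gives the same value with the sign turned, so it cannot show that samples were paired. The labels do not say that a number marks a shared litter or day. Single genes and lists were compared over the alternatives that used the preset correlation, and the counts of calls over all of them. Of these results 1616 stayed as they were, 146 moved, 52 gained and 11 lost a call, and 4 reversed, of which the cholesterol list also lost its call. With an estimated correlation, and with fry, all 12 list calls were lost. Depth is unknown, so its limit on low genes could not be given.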

Other observations

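The test on meningeal markers was written before its values were seen, although 3 of its genes belong to the fixed fibroblast and meninges list whose fall had been seen. The other tests were chosen after the result was seen. Solute carrier genes, which encode membrane transporters, made up 20 of the 129 lower genes in the authors' deposited table (15.5%) and 246 of the 14040 tested genes (1.75%). By Fisher's exact test, two-sided, the odds ratio was 11.1 (p = 8.91e-14, Benjamini-Hochberg adjusted 1.78e-13 over 2 directions). Of the 20 higher genes matched by name, 0 were solute carriers. Genes are not independent replicates, and the group was picked because it stood out. Slc22a6 was at 17.2 and 13.3 FPKM in wild type and at 3.62 and 2.94 FPKM in the mutants, and Slc38a3 at 13.5 and 12.5 against 3.76 and 3.99 FPKM. Among the lists fixed beforehand, 1 gene of the nociceptor lists, Prdm12, was in the authors' list.

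Apart from Prdm12, the 128 lower genes of the authors' list had a median log2 difference of -1.23 (quartiles -1.50 and -1.03), and the most abundant, Ptgds, is known from the meninges. Scaling does not account for it, since the median was -1.21 after rescaling by median ratios, nor does wild type 2 alone, since it was -1.39 without that sample. A candidate explanation is less meningeal tissue in the mutant samples: 24 meningeal markers outside the authors' list had a median of -0.56 (quartiles -0.73 and -0.29), with 14 lower and 1 higher without overlap, including Foxc1 at 33.3 and 31.1 FPKM in wild type against 22.4 and 12.2 in the mutants. The median lay below all of 10000 random lists matched on expression, but such lists ignore that markers of 1 tissue move together, and with an estimated correlation of 0.53 the markers did not pass camera (p = 0.171). Against the wild type mean, the markers' median was -0.18 in mutant 1 and -0.88 in mutant 2, where the pattern's was -1.02 and -1.44, so the fall of the markers stood mostly in mutant 2. How much of the pattern it may account for stays open, since the markers were taken outside the authors' list, and fibroblasts of the ganglion also express several of them. An effect of the genotype on these cells stays open and was not tested, since the 2 groups of 2 confound it with dissection.

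Skeletal muscle genes differed between samples of the same group. In the 18 muscle markers of the fixed list, replicate 2 exceeded replicate 1 by a median of 2.68 log2 units in wild type (17 of 18 higher) and 4.58 in the mutants (18 of 18). Adipocyte markers went the same way, by 0.80 and 2.98 log2 units. Of the markers in the 2 fixed lists, the authors' list holds 6 of muscle, 2 higher and 4 lower, and 3 of adipocytes, all higher. It also holds muscle genes outside those lists, such as Csrp3 and Mybpc1, both lower. Of its 20 higher genes matched by name, all 20 were above the wild type mean in mutant 2 and 8 in mutant 1. What set these samples apart stays open.

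Of 28 histocompatibility genes named H2, 11 were higher and 5 lower in both mutants than in both wild types, and 12 overlapped. Among those that overlapped, H2-Q2 was at 3.42 and 0.104 FPKM in wild type and at 0.0328 and 5.15 FPKM in the mutants, and H2-T10 at 6.59 and 1.70 against 1.05 and 6.24 FPKM. H2-Ea-ps separated the groups, at 1.87 and 1.35 FPKM in wild type and listed at 0 in both mutants (genes named after their values were seen). More macrophages in both mutants do not account for H2-Eb1, at a log2 difference of 1.41. The macrophage markers' median was -0.0072 (quartiles -0.10 and 0.08). Their median deviation from the mean of the 4 samples was 0.23 in mutant 1 and -0.23 in mutant 2. H2-Eb1 was at 198 and 129 FPKM in these samples. More macrophages in mutant 1 alone would leave the rise in mutant 2 without an account, since H2-Eb1 was at 51.3 and 69.4 FPKM in wild type. What part macrophages had in the value of mutant 1 stays open. The list also cannot show a change in other cells that may express class II genes, which was not tested. The median range over the 4 samples was 1.27 log2 units for the 28 genes, against 0.54 for 32 macrophage, lymphocyte and neutrophil markers. Haplotypes of the mixed strain background, reads shared between these near-identical genes, and variants against the reference were not tested.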
